A study of Mus musculus with 6 samples.

How the data were processed

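Haematopoietic stem cells (HSCs) were sorted from the bone marrow of mice in which a tetracycline-controlled transactivator, expressed from the endogenous Scl (Tal1) locus, switched on a fusion of histone H2B and green fluorescent protein (GFP). Doxycycline switches this system off, so that the stable fusion protein is then diluted with each division. Per the labels, cells were collected after 170 days of doxycycline, gated as lineage-negative, Sca1-positive, c-Kit-positive, CD150-positive, CD48-negative and CD34-negative, and then parted by GFP. GFP-positive cells are called label-retaining cells (LRC) here, and GFP-negative cells non-LRC. Each group had 3 samples, described in the labels as independent biological replicates; whether a sample was 1 mouse or a pool is not given in the sources used here.

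Total RNA was isolated with a kit for very small cell numbers, amplified in 2 rounds with the NuGEN WT-Ovation Pico system and biotin-labelled with an Affymetrix kit, per the labels' protocols. Each sample was hybridized to 1 mouse expression array. The deposited values are log2 expression values, 1 per probe set and sample. RMA, which corrects background, quantile-normalizes arrays and summarizes probes, is named in the submitters' processing notes with no version. The log base was taken from the range of the deposited values and is not given in the sources used here, nor are the software and its background model. Quantile normalization forces the arrays to nearly equal distributions, so a change of total RNA per cell cannot be seen in these values. Arrays carry no read depth; their number limits the precision.

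Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested. Gene symbols came from an annotation of the array platform, whose older symbols were updated through gene identifiers to a RefSeq gene table of the mouse assembly GRCm38.p6, used for names and for sex-chromosome linkage only. Of the probe sets tested, 34945 named 1 gene, 932 named several and 9160 had no gene symbol there. Genes were named only from probe sets with 1 symbol, which gave 18194 genes. For gene lists and for the genes always reported, a gene was represented by its probe set of highest mean over all 6 arrays. Columns of other samples numbered 0.

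The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, LRC minus non-LRC, no covariate). P-values were adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. Errors of single-gene differences are limma's moderated standard errors. Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01, for the 30 of 31 lists that had at least 5 measured members. Adjusted p-values of lists are Benjamini-Hochberg values over those 30 tests. Camera was also run with the correlation estimated from the residuals, and fry was run beside it. Means of a list or control measure per array were compared by two-sided exact permutation tests, which with 3 against 3 samples cannot give a p below 0.1.

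The 31 lists held 1167 entries, of which 1016 were measured. They covered dormancy and cycling, metabolism, signalling, stress and immunity, the blood lineages, and endothelial and stromal cells that a bone marrow sort could hold. The lists, the tests and the rule for naming genes were fixed before the data were examined. A synonym match that had placed a mitochondrial ribosomal protein gene in the cytosolic list was removed after first results had been seen. The rule named, first, in each direction 12 genes past the threshold with all 3 LRC values on the same side of all 3 non-LRC values, filled up by smallest p where too few passed. It then named up to 4 members of each list by smallest p, and always the genes of the gate, Tal1, Flt3, Mki67 and Cdkn1c. Genes of the gate or lists without a probe set of their own symbol are not analysed here.

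The tests were run first on simulated data with known answers. In arrays simulated for LRC against non-LRC over 45037 probe sets, 50 probe sets were changed at each of 4 sizes. At the 0.05 threshold, 0% were recovered at a log2 change of 1, 60% at 2, 82% at 3 and 88% at 4, with 7 false calls. Among 30 simulated lists of 40 genes each, drawn from 18194 genes, 3 lowered by a log2 change of -0.5 were all called, with 0 false calls, at either correlation setting. The simulated genes varied independently, so this run could not show false calls that arise from correlation between genes.

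Other settings listed beforehand were another quantile normalization, median centring, leaving out probe sets whose mean lay below the 40th percentile, trend and robust moderation, array weights, the replicate number as a block, leaving out each array in turn, a threshold of 0.1, an unadjusted p under 0.05 with a change of at least 2-fold, and the mean of all probe sets of a gene. For lists, the estimated correlation and fry were listed too. After the data were seen, 6 more were added: the Xist level as a block, both high-Xist arrays left out, cyclic loess, the hybridization control level as a covariate, that covariate together with an estimated correlation for the lists, and both LRC arrays with bright hybridization controls left out, which leaves 1 LRC array whose spread is assumed to be that of the non-LRC arrays.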

Results

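Expression was measured in 3 samples of label-retaining HSCs, which were GFP-positive after 170 days of doxycycline. The 3 samples of non-LRC HSCs came from the same surface-marker gate and were GFP-negative. Retained label is taken to mark cells that divided little during the chase. GFP-negative cells may have diluted the label by division or may never have carried it. All samples were collected after the chase, so these possibilities cannot be told apart here. The comparison thus asks which genes differ between GFP-positive and GFP-negative HSCs, and division itself was not measured. Array medians lay between 4.33 and 4.39 on the log2 scale. Pearson correlations between arrays, across probe sets, ran from 0.901 to 0.970. The array of LRC replicate 1 correlated least with the rest, at 0.901 to 0.919.

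As a list, genes of the G1 to S transition and DNA replication were called lower in LRC by camera with its preset correlation (mean difference -0.61, adjusted p = 1.79e-11), but not with an estimated correlation (adjusted p = 0.506) or by fry (adjusted p = 0.590). Of 53 measured members, 45 had a lower mean in LRC, and 0 passed the threshold on their own. For 16 all 3 LRC values lay below all 3 non-LRC values, where independent genes would give 5% by chance and other splits of the arrays gave at most 6. The list mean was 6.60 ± 0.27 in LRC and 7.21 ± 0.14 in non-LRC (log2, SD, n = 3 each), a 1.52-fold lower level in LRC. Gins1, a subunit of the replicative helicase complex, had values of 5.25 ± 0.41 in LRC and 6.61 ± 0.55 in non-LRC. Cdc6, which loads that helicase onto origins, differed by -1.76 (SE 0.56), Gmnn, the inhibitor of origin relicensing, by -1.17 (SE 0.35), and Mcm6, a helicase subunit, by -0.62 (SE 0.20, with 1 of its 2 other probe sets of the same sign).

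Every LRC array had a lower mean of the replication list than every non-LRC array. An exact permutation test of the list means gave p = 0.1, the smallest it can give. No member passed the threshold over all probe sets, and 0 did when adjusted over the list alone. The hybridization controls, bacterial and phage transcripts spiked into the sample, were brighter on LRC replicates 1 and 3 (11.42 and 11.24) than on any other array (10.80 to 10.90). With their level as a covariate the list difference was -0.36 (adjusted p = 0.0264, and 0.645 when the correlation was also estimated). This fit rests largely on LRC replicate 2 (controls at 10.81), the 1 LRC array without bright controls, so its p-values are weakly replicated. Leaving out both arrays leaves 1 LRC array, replicate 2, so its p-values assume that this array varies like the non-LRC arrays and are no replicated test. The difference was then -0.36 (adjusted p = 0.0464).

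Mitotic genes were also called lower in LRC as a list by camera with its preset correlation (mean difference -0.49, adjusted p = 1.82e-07), but not with an estimated correlation (adjusted p = 0.891) or by fry (adjusted p = 0.895). Of 55 measured members 43 had a lower mean in LRC, and 0 passed the threshold over all probe sets. For 9 all LRC values lay below all non-LRC values, where independent genes would give 5% by chance and another split of the arrays gave 11. The list mean was 5.87 ± 0.33 in LRC and 6.36 ± 0.24 in non-LRC (SD, n = 3 each), a 1.41-fold lower level. Cdc20, an activator of the anaphase-promoting complex, had the largest difference among the members named, at 5.24 ± 0.80 against 7.76 ± 0.17, a difference of -2.52 (SE 0.41). It was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0379), but its adjusted p over all probe sets was 0.998. Ccna2, cyclin A2, differed by -1.96 (SE 0.66), Cks2, a subunit of cyclin-dependent kinases, by -1.42 (SE 0.50), and Bub1, a spindle checkpoint kinase near the floor of the array in LRC, by -1.03 (SE 0.29), although its 1 other probe set had the opposite sign.

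The exact permutation p of the mitosis list means was 0.2. LRC replicate 2, at 6.13, lay above non-LRC replicate 2, at 6.10. The mean difference was -0.31 without LRC replicate 1 (adjusted p = 0.00206). With the hybridization control level as a covariate it was -0.20 and the call was lost (adjusted p = 0.333). With LRC replicate 2 as the only LRC array it was -0.23 (adjusted p = 0.196).

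MYC and ribosome biogenesis genes were called lower in LRC as a list by camera with its preset correlation (mean difference -0.24, adjusted p = 0.000151), but not with an estimated correlation (adjusted p = 0.891) or by fry (adjusted p = 0.952). Of 52 members 39 had a lower mean in LRC. For 9 all LRC values lay below all non-LRC values, and another split of the arrays gave 8. Its mean was 7.95 ± 0.26 in LRC and 8.19 ± 0.09 in non-LRC (SD, n = 3 each), a 1.18-fold lower level. Nop58, a component of box C/D small nucleolar ribonucleoproteins, differed by -0.66 (SE 0.24), Wdr43, whose 1 other probe set had the opposite sign, by -0.79 (SE 0.29), Nob1, an endonuclease of ribosomal RNA maturation, by -0.75 (SE 0.30), and Gnl3, nucleostemin, by -0.67 (SE 0.28). Adjusted over the list alone, 0 members passed. Myc itself differed by -0.76 (SE 0.37), or by -0.46 without LRC replicate 1, and did not pass.

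The exact permutation p of the MYC list means was 0.3. LRC replicate 2, at 8.23, lay within the non-LRC range of 8.10 to 8.27. Without LRC replicate 3 the difference was -0.12 and the call was lost (adjusted p = 0.185), and without LRC replicate 2 it was -0.38 (adjusted p = 3.58e-07). With the hybridization control level as a covariate it was -0.05 and the call was lost (adjusted p = 0.894). With LRC replicate 2 as the only LRC array it was 0.04 (adjusted p = 0.581).

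**Figure D1:**
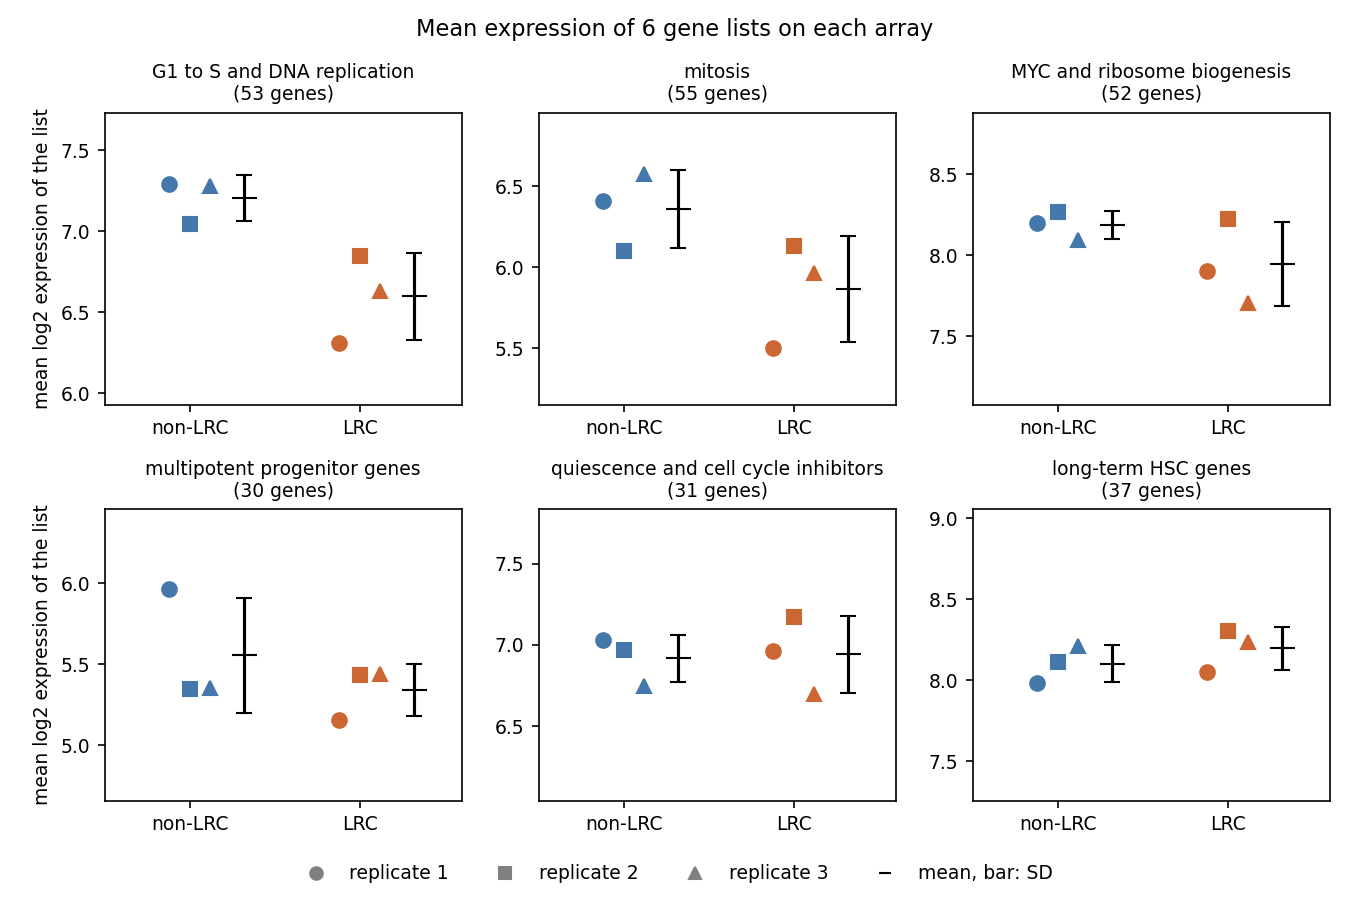
Mean log2 expression of 6 gene lists on each array (vertical axis, each panel spanning the same range) for non-LRC (blue) and LRC (orange), with 1 symbol per replicate and the group mean ± SD in black. The 3 LRC arrays lie below the 3 non-LRC arrays in the list of G1 to S and DNA replication genes, while the groups overlap in the other 5 lists.

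At the level of single probe sets, no gene passed the threshold in either direction. Limma called 0 of 45037 probe sets, 0 higher and 0 lower in LRC, and the smallest adjusted p was 0.658. At an unadjusted p under 0.05 there were 1673 probe sets, 785 higher and 888 lower in LRC, where chance alone would give 2252. The share of probe sets whose groups did not overlap was 8.28%, against 10% by chance. Adding a change of at least 2-fold to the unadjusted threshold left 774 probe sets, 318 higher and 456 lower. In the simulated arrays a log2 change of 1 was recovered in 0% of cases, so differences of that size were not detectable with this number of arrays.

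The genes with the smallest p among those with separated groups are therefore given as values that did not pass. Prkd1, protein kinase D1, was at 1.97 ± 0.13 in LRC and 5.83 ± 0.69 in non-LRC (log2, SD, n = 3 each), a difference of -3.87 (SE 0.36, adjusted p = 0.658). The LRC values of Prkd1 and of Maf (mean 2.33) lay near the floor of the array, so the size of both differences is uncertain. Maf, a bZIP transcription factor, differed by -3.28 (SE 0.47), although only 1 of its 5 other probe sets had the same sign. Zg16, a secretory granule lectin, differed by -3.06 (SE 0.48), Cdc20 by -2.52 and Ncoa7, a nuclear receptor coactivator, by -1.89 (SE 0.26). Cdca8, a subunit of the chromosomal passenger complex that acts in mitosis, differed by -1.19 (SE 0.20), with both other probe sets of the same sign. The 6 others below were Ric8b, Btbd9, Znrf2, Lsm6, BC003965 and Mcur1, at -1.71 to -1.03.

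In the other direction, Txnrd2, the mitochondrial thioredoxin reductase, differed by 2.64 (SE 0.47), with all 3 of its other probe sets of the same sign. Them4, an acyl-CoA thioesterase, differed by 2.36 (SE 0.38), Patj, a cell polarity protein, by 2.27 (SE 0.36), and Efr3a, a plasma membrane scaffold of a phosphatidylinositol kinase, by 1.86 (SE 0.28). Stat3, a transcription factor of cytokine signalling, was at 7.75 ± 0.07 in LRC and 6.53 ± 0.23 in non-LRC, with 2 of 3 other probe sets of the same sign. Exosc10, Rcan1, Usp53, Coro1a, Ptpn3, Trim3 and Ikbkg made up the 12 and differed by 2.08 to 1.15. Adjusted p was 0.998 for all 24 genes except Prkd1. Of the 22 of these genes with other probe sets, all of them had the same sign in 8, some in 9 and none in 5 (Rcan1, Coro1a, Ric8b, Btbd9 and Mcur1).

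**Figure D2:**
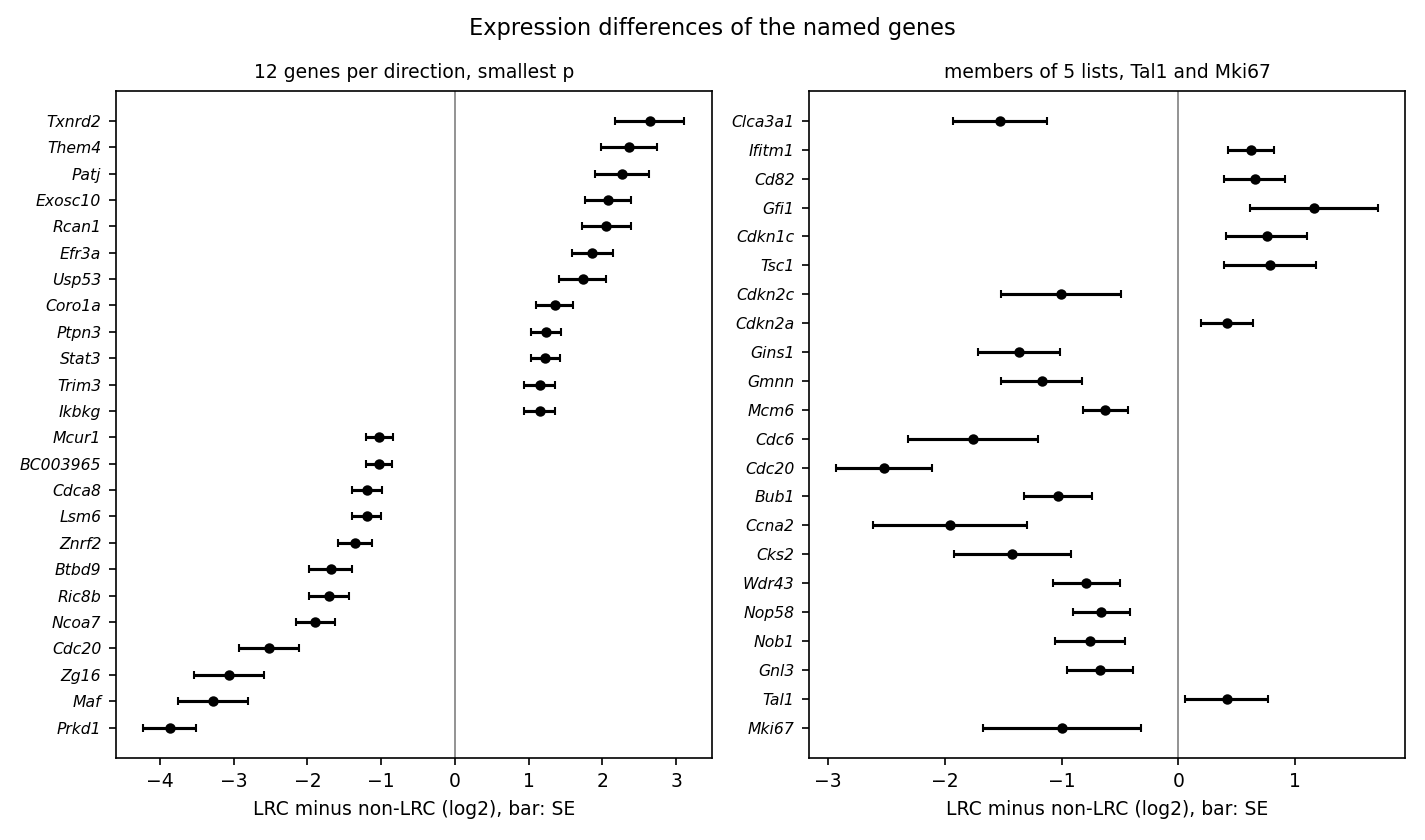
Differences between LRC and non-LRC (horizontal axis, log2, bars are the moderated SE) for the 24 genes with the smallest p and separated groups (left) and for named members of 5 gene lists with Tal1 and Mki67 (right). All 12 named members of the replication, mitosis and MYC lists lie to the left of 0, and none of the genes shown passed the threshold over all probe sets.

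Genes of the sorting gate gave a check of the populations. Kit, positive in the gate, was at 9.07 ± 0.07 in LRC and 9.05 ± 0.06 in non-LRC, and Slamf1, which encodes CD150, at 7.61 ± 1.30 and 7.98 ± 0.68 (log2, SD, n = 3 each). Cd48, negative in the gate, was near the floor of the array, at 2.60 ± 0.25 and 2.73 ± 0.48. Cd34, also negative in the gate, was not near the floor on most arrays: it was at 7.43, 6.60 and 5.62 in non-LRC and at 2.52, 6.97 and 5.10 in LRC, where array medians were at most 4.39. Its mean was 4.86 ± 2.23 in LRC and 6.55 ± 0.90 in non-LRC, a difference of -1.69 (SE 1.12) that did not pass and was -2.74 without LRC replicate 2. Tal1, whose locus drives the label, differed by 0.41 (SE 0.36), with 0.17 to 0.67 when single arrays were left out, and Flt3, a progenitor receptor, by -0.27 (SE 0.61), with -0.93 to 0.26. Mki67, the proliferation antigen, was at 9.23 ± 1.33 in LRC and 10.23 ± 0.51 in non-LRC and did not pass. The 4 gate genes measured were too few for a list test; their mean was 6.04 ± 0.76 in LRC and 6.58 ± 0.02 in non-LRC, and 0 passed when adjusted over the list alone. Much of this rested on LRC replicate 1: without it the mean of the gate genes differed by -0.11 rather than -0.54, Cd34 by -0.52 and Mki67 by -0.23, and Slamf1 by 0.31 rather than -0.37.

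Genes of long-term HSCs and of quiescence did not pass as lists. In the list of long-term HSC genes 21 of 37 members had a higher mean in LRC (mean difference 0.10, camera adjusted p = 0.402). That difference was 0.04 without non-LRC replicate 1, 0.04 without LRC replicate 2 and 0.17 without LRC replicate 1. Ifitm1, an interferon-induced membrane protein, differed by 0.62 (SE 0.20), Cd82, a tetraspanin, by 0.65 (SE 0.26), Gfi1, a repressor that restrains HSC proliferation, by 1.16 (SE 0.55), or by 0.69 without non-LRC replicate 2, and Clca3a1 by -1.53 (SE 0.40). Of the quiescence and cell cycle inhibitor genes 16 of 31 had a higher mean (mean difference 0.03, adjusted p = 0.970). With LRC replicate 2 as the only LRC array, which is no replicated test, that list was called as higher in LRC (mean difference 0.26, adjusted p = 0.0464), the 1 of 22 alternatives that called it (adjusted p 0.0464 to 0.983), and so was the list of long-term HSC genes (0.20, adjusted p = 0.0464). Cdkn1c, which encodes the cell cycle inhibitor p57, was at 8.07 ± 0.60 in LRC and 7.31 ± 0.28 in non-LRC, a difference of 0.76 (SE 0.35) with an adjusted p of 0.998. Multipotent progenitor genes had 18 of 30 members at a lower mean in LRC (mean difference -0.21, adjusted p = 0.175). Non-LRC replicate 1, at 5.96, lay above the other 5 arrays, and without it the mean difference was -0.008 (camera adjusted p = 0.934). The 5 measured replication-dependent histone genes gave a mean difference of -0.08 (adjusted p = 0.708).

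Metabolic and housekeeping groups did not pass. Mitochondrial respiration genes had 54 of 83 members at a lower mean in LRC, with a mean difference of -0.13 (adjusted p = 0.0915). That difference was -0.03 without LRC replicate 1 (adjusted p = 0.921) and -0.25 without LRC replicate 2, where the list was called (adjusted p = 0.000309). With the hybridization control level as a covariate it was 0.09 and called as higher in LRC (adjusted p = 0.0449, and 0.645 when the correlation was also estimated). With LRC replicate 2 as the only LRC array, which is no replicated test, it was 0.11. Over 22 alternatives the list was called in 5 (adjusted p 0.000309 to 0.952), 1 of which only raised the threshold to 0.1. Glycolysis and hypoxia genes had a mean difference of -0.09 (adjusted p = 0.444) and cytosolic ribosomal protein genes one of 0.01 (adjusted p = 0.826), or 0.13 and called as higher with that covariate (adjusted p = 0.0264, and 0.718 when the correlation was also estimated), the 1 of 22 alternatives that called it (adjusted p 0.0264 to 0.998). Membrane transporters and detoxification genes had 25 of 34 members at a lower mean (mean difference -0.15, adjusted p = 0.175), while Abcb1a, a drug efflux pump, differed by 0.85 (SE 0.34), or by 0.51 without LRC replicate 3. With the hybridization control level as a covariate the transporter list differed by 0.06 (adjusted p = 0.269). For chromatin regulators the mean difference was -0.09 (adjusted p = 0.175), and 0.11 with that covariate (adjusted p = 0.451). DNA damage response and repair genes gave -0.06 (adjusted p = 0.708) and apoptosis regulators -0.08 (adjusted p = 0.708). Msh6, a mismatch repair gene, was at 8.30 ± 0.15 in LRC and 9.11 ± 0.04 in non-LRC, and Atm, the double-strand break kinase, differed by 0.86 (SE 0.31), although its 1 other probe set had the opposite sign. Cflar, an inhibitor of caspase activation, differed by 0.69 (SE 0.20), with 3 of 4 other probe sets of the same sign.

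Signalling and immune lists did not pass either. Wnt and Notch signalling genes had a mean difference of 0.10 (adjusted p = 0.466), although all 3 LRC list means (5.79 to 5.90) lay above all 3 non-LRC list means (5.68 to 5.79), with an exact permutation p of 0.1, the same as for the replication list. The mean difference was -0.08 for TGF-beta and BMP signalling (adjusted p = 0.735) and -0.01 for niche signalling receptors and adhesion (adjusted p = 0.875). Lrp6, a Wnt co-receptor, differed by 0.93 (SE 0.34), although its 1 other probe set had the opposite sign. Bmpr1a, a BMP receptor, differed by -1.52 (SE 0.65), or by -0.83 without LRC replicate 1, with 3 of 5 other probe sets of the same sign. Interferon response genes had a mean difference of 0.01 (adjusted p = 0.855), with Irf1 at 0.53 (SE 0.21) and Rtp4 at -0.92 (SE 0.29). The list difference was 0.18 without LRC replicate 1 (adjusted p = 0.198). It was 0.28 with the hybridization control level as a covariate and called as higher in LRC (adjusted p = 0.0418, and 0.645 when the correlation was also estimated). With LRC replicate 2 as the only LRC array, on which the covariate fit also largely rests, it was 0.25. These were the 2 of 22 alternatives that called it (adjusted p 0.0418 to 0.995). MHC and antigen presentation genes gave -0.04 (adjusted p = 0.882) and immediate early and stress genes -0.11 (adjusted p = 0.708). In the interferon, niche, MHC, apoptosis, B cell and ribosomal protein lists the mean, the median or the camera direction differed in sign.

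Markers of blood lineages and of other marrow cells were compared as well. Megakaryocyte and platelet genes came closest to the threshold, with 18 of 26 at a lower mean in LRC (mean difference -0.23, adjusted p = 0.0510, and 0.891 with an estimated correlation). The list was called in 8 of 22 alternatives (adjusted p 0.00213 to 0.952), 1 of which only raised the threshold to 0.1. Among them were those without non-LRC replicate 1 (-0.31) and without LRC replicate 2 (-0.37). With the hybridization control level as a covariate the list's mean difference was 0.02 (adjusted p = 0.632). It was weaker and not called without non-LRC replicate 3 (-0.13, adjusted p = 0.495) and without LRC replicate 1 (-0.16, adjusted p = 0.253). Vwf, von Willebrand factor, was at 7.64 ± 1.23 in LRC and 8.84 ± 0.39 in non-LRC, a difference of -1.20 that was -0.57 without LRC replicate 1. Plek, a platelet kinase substrate, differed by -1.27 (SE 0.53), or by -0.81 without LRC replicate 3, with 1 of its 2 other probe sets of the same sign. Erythroid genes gave a mean difference of -0.09 (adjusted p = 0.735), granulocyte and monocyte genes 0.06 (adjusted p = 0.708), and mast cell, basophil and eosinophil genes 0.26 (adjusted p = 0.183). The mean of the mast cell list was 4.22 on LRC replicate 1 and 3.52 to 3.75 on the other 5 arrays; its difference was 0.07 without LRC replicate 1 and -0.06 with the hybridization control level as a covariate (adjusted p = 0.707). B cell genes gave 0.02 (adjusted p = 0.879), T and NK cell genes 0.05 (adjusted p = 0.775) and dendritic cell genes 0.03 (adjusted p = 0.974). Endothelial genes gave -0.14 (adjusted p = 0.766) and stromal and bone genes 0.10 (adjusted p = 0.508).

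Camera thus called 3 of 30 lists, all lower in LRC, and 0 of 30 with an estimated correlation or with fry. Adjusted over the list alone, 0 members passed in the 30 lists other than mitosis. The number of lists called was 9 without LRC replicate 2, 5 without non-LRC replicate 1 and 2 without LRC replicate 3. Without LRC replicate 2 the added lists were mitochondrial respiration, glycolysis and hypoxia, megakaryocyte and platelet, mast cell, transporter and chromatin regulator genes. Without non-LRC replicate 1 they were megakaryocyte and platelet genes and chromatin regulators, and without non-LRC replicate 2 multipotent progenitor genes were added (adjusted p = 0.0373). Of the 27 lists not called, 6 had a mean difference of the other sign without LRC replicate 1, and in 14 more it moved by over 1.5 times. These numbers were 7 and 10 without LRC replicate 3. Without any 1 of the remaining arrays they were 2 to 5 and 9 to 14.

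Sex-linked genes differed between replicates within each group. Xist, expressed from the inactive X chromosome, was at 11.65 in non-LRC replicate 2 and 11.58 in LRC replicate 2, and at 3.54 to 5.13 on the other 4 arrays. Eif2s3y, a Y-linked gene, was at 2.28 and 2.82 on the same 2 arrays and at 7.86 to 8.74 on the others. Each group thus held 1 array with high Xist and low Eif2s3y. The list of sex-linked genes had a mean difference of -0.25 between LRC and non-LRC (adjusted p = 0.708). With LRC replicate 2 as the only LRC array it was -0.90. That contrast sets a high-Xist array against non-LRC arrays of mostly low Xist, so it cannot part label retention from the Xist level.

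**Figure D3:**
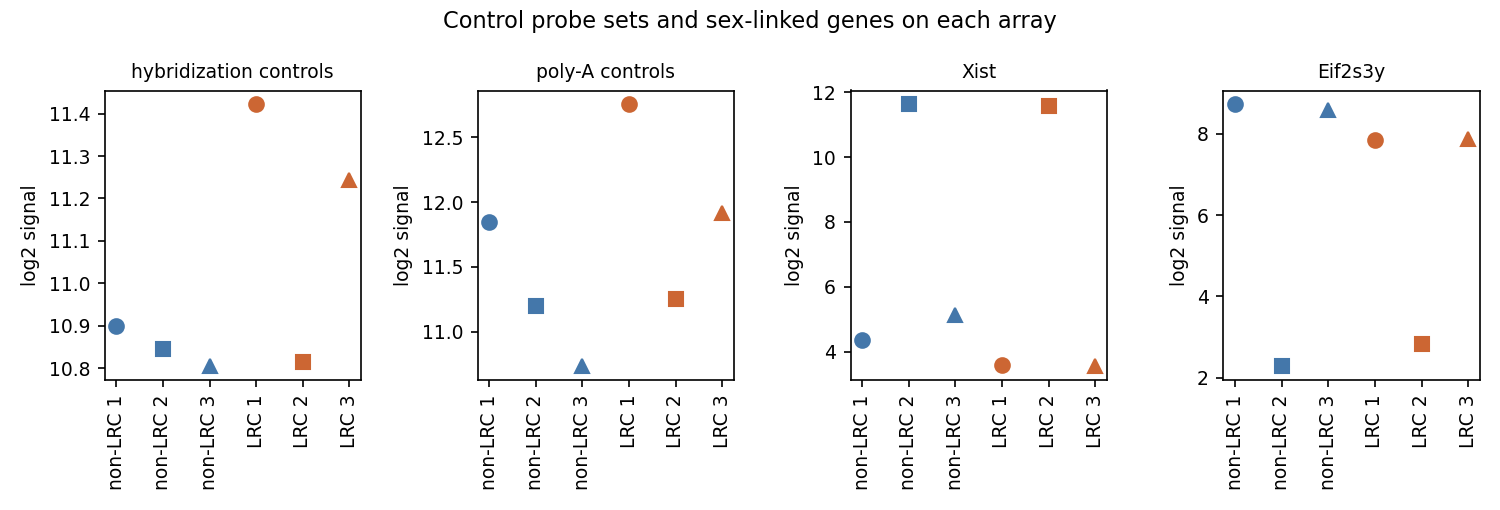
Log2 signal of hybridization controls, poly-A controls, Xist and Eif2s3y (vertical axes, each with its own range not starting at 0) on the 6 arrays, with non-LRC in blue and LRC in orange and 1 symbol per replicate. The hybridization controls were brightest on LRC replicates 1 and 3, at 11.42 and 11.24, and Xist was high on replicate 2 of each group.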

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

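The tests on control probe sets and cyclic loess were chosen after the results had been seen; leaving out each array was chosen before, but the bounds for reading every test in this part were set after its values were known. The bounds on what remains of a list difference were also replaced then. Under the control covariate an earlier, narrower bound left the mitosis list undecided. By that of 1 standard error used here, a lower RNA yield is a candidate for it. Control probe sets, which entered no comparison, were brighter on 2 LRC arrays than on any non-LRC array. The mean of the hybridization controls was 11.4 on LRC replicate 1 and 11.2 on LRC replicate 3, against at most 10.9 in non-LRC. The poly-A controls, which are usually added to the RNA before amplification, were at 12.8 and 11.9 on the same arrays, against at most 11.8. Exact permutation tests gave p = 0.3 for the hybridization controls and p = 0.2 for the poly-A controls. The 3' minus 5' signal of Gapdh, a measure of RNA quality, was 4.16 on LRC replicate 1 against at most 3.42 in non-LRC (exact permutation p = 0.6), and that of Actb gave an exact permutation p of 1.

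The lower level of replication, mitosis and MYC genes in LRC may follow from slower division of label-retaining cells or from the arrays. Other differences between GFP-positive and GFP-negative cells are open too. Division was not measured, and GFP-negative cells may never have carried the label. A trend with brightness alone is argued against by cyclic loess, which left mean differences of -0.59, -0.49 and -0.20 for the 3 lists. It kept all 3 calls at the preset correlation. The medians of the 3 lists lay at percentiles 0, 0 and 0.02 of 10000 random lists of matched mean expression. Random lists hold unrelated genes, however, and do not carry the correlation within a list. Lists not called also lay far out, multipotent progenitor genes at 0.09 and long-term HSC genes at 99.99. LRC replicate 1 alone is argued against for the replication list, which without it still differed by -0.47 (95% interval -0.89 to -0.04); for mitosis (-0.31, -0.92 to 0.30) and MYC genes (-0.22, -0.87 to 0.43) the interval held 0. A lower RNA yield on LRC replicates 1 and 3 is a candidate explanation for the MYC list and, only by the later bound, for mitosis. Bright controls are an indirect sign of such a yield. With the control level as a covariate the MYC list differed by -0.048 (SE 0.17, 95% interval -0.59 to 0.49, from -0.24 with SE 0.16). The mitosis list differed by -0.20 (SE 0.25, 95% interval -0.99 to 0.58, from -0.49 with SE 0.24). For the replication list the difference was -0.36 (SE 0.15, 95% interval -0.85 to 0.12, from -0.61 with SE 0.18). All 3 intervals hold both 0 and the difference without the covariate. Yield and label retention thus cannot be told apart for any of the 3 lists, with 3 residual degrees of freedom and controls that go with the group. Only the hybridization controls were used as a covariate. On the poly-A controls LRC replicate 1 (12.76) stood apart, while LRC replicate 3 (11.91) was level with non-LRC replicate 1 (11.84). The replication list mean was 7.29 on that non-LRC array and 6.63 on LRC replicate 3.

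The 6 arrays make 10 splits into 3 against 3, too few for a share under 0.05. Limma called 0 probe sets for the real groups, in either direction, and at most 0 in the other splits, so that all 10 splits gave as many; at an unadjusted p under 0.05 the real groups gave 1673 and the highest other split 3774. The real groups gave 3 called lists and the highest other split 13, and 7 of the 10 splits called at least as many. That highest split set LRC replicates 1 and 3 with non-LRC replicate 1 against the rest, the 3 arrays with the brightest controls, which points to a structure of the samples other than the groups. The mean of the replication list differed by 0.61 in size for the real groups, the largest of the 10 splits (1 as large), and by at most 0.48 in the others. For mitosis the sizes were 0.49 and at most 0.52, and for MYC genes 0.24 and at most 0.33. Members with fully separated groups in the same direction numbered 16 for replication and at most 6 in the other splits, 9 and at most 11 for mitosis, and 9 and at most 8 for MYC genes.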

How the results depend on the processing

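The alternatives on Xist, on hybridization controls and on cyclic loess were chosen after seeing the data. Limma called 0 probe sets under every alternative at an adjusted threshold, including without each array in turn (0 to 0), and with a replicate block (0, with 2017 at an unadjusted p under 0.05, and 4 lists called, the fourth megakaryocyte and platelet genes). An unadjusted p under 0.05 with a 2-fold change gave 774 (318 higher, 456 lower), by construction a looser rule. Without each array in turn 2 to 9 lists were called, the 9 without LRC replicate 2, 5 without non-LRC replicate 1 and the 2 without LRC replicate 3. The estimated correlation, alone (0) or with the hybridization control covariate (0), and fry called 0 lists, and a threshold of 0.1 called 5. Without both high-Xist arrays 6 were called, including all 3. Across 22 alternatives the replication list was called in 19 (adjusted p 6.51e-12 to 0.645), mitosis in 17 (1.93e-11 to 0.895) and MYC genes in 16 (3.58e-07 to 0.981). Without the alternative that only raised the threshold to 0.1, these counts were 18, 16 and 15. Every one of these calls used camera's preset correlation, so the counts do not bear on that setting.

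With the hybridization control level as a covariate 6 lists were called, and among these camera's direction turned to higher for ribosomal proteins (mean 0.135), mitochondrial respiration (0.0869) and interferon response (0.278). Leaving out both bright LRC arrays leaves 1 LRC array. Mean differences were then above 0 for MYC genes (0.0402), mitochondrial respiration (0.106), interferon response (0.246), ribosomal proteins (0.136) and transporters (0.0854), among others. The cause was not tested. The means of ribosomal proteins and interferon response were already above 0. Means changed sign in 12 of 30 lists with the covariate and 13 without both arrays. Same-numbered arrays' deviations from the group means correlated by 0.0798, 0.141 and 0.0811, not all high enough to treat the samples as paired; every array correlated best with its own number, a hint that leaves pairing open. Of 144 named genes 21 changed sign under some alternative. None were among the 24 chosen for separated groups. Leaving out arrays cannot turn their differences, so this is no evidence of their stability. Precision is limited by 6 arrays and, for dim genes such as Cd48, by signal near background.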

Other observations

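MHC and antigen presentation genes, of class I and class II, did not pass as a list, with 9 members at a higher and 8 at a lower mean in LRC. H2-D1, a class I heavy chain, differed by 0.51 between LRC and non-LRC (log2, SE 0.34), and all 8 of its other probe sets had the same sign. Tapbp, which loads peptides onto class I molecules, differed by 0.56 (SE 0.28), and Cd74, the class II invariant chain, by 0.86 (SE 0.42). H2-Ob, a class II chain, differed by -1.83 (SE 1.12), and none of these passed. H2-Ob lay near the floor of the array on LRC replicates 1 and 3 (2.46 and 2.34) and on non-LRC replicate 1 (2.43), so the size of its difference is uncertain. Without non-LRC replicate 1 H2-D1 differed by 0.20, Tapbp by 0.36 and H2-Ob by -3.02, without LRC replicate 1 H2-D1 by 0.30, without LRC replicate 2 Cd74 by 0.43 and Tapbp by 0.36, and without non-LRC replicate 3 H2-Ob by -0.88. With the hybridization control level as a covariate, an alternative chosen after seeing the data, the list was called as higher in LRC (mean difference 0.41, adjusted p = 0.00353), and the list of long-term HSC genes too (0.23, adjusted p = 0.0223). Both calls rest on camera's preset correlation and were lost when the correlation was estimated in the same fit (adjusted p = 0.645 for each). The covariate fit also rests largely on LRC replicate 2, the 1 LRC array without bright controls. Over 22 alternatives the adjusted p ran from 0.000435 to 0.980 for the MHC list and from 0.0223 to 0.896 for the long-term HSC list, and each was called in 2, this one and that with LRC replicate 2 as the only LRC array.

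The tests of the replicate numbers below were chosen after the results had been seen. Both arrays numbered 2 stood apart from the other 4 by over 2 log2 units at 19 probe sets with 1 named gene. Of these, 9 were sex-linked, 3 of Xist, higher, and 6 of the Y-linked genes Eif2s3y, Uty and Kdm5d, lower, so that all 9 went in the direction of female mice, a likely source of this part. The other 10 were not placed on X or Y by the RefSeq annotation, and sex alone need not move autosomal genes. A gene without a match there was counted among these 10. AI506816 was at 7.56 on average against 2.39, LOC664787 at 8.10 against 3.46, Myl10 at 10.40 against 6.20, Mmab at 8.04 against 4.31 and Prss22 at 8.24 against 4.18, while Fanci was lower, at 3.23 against 6.26. These genes were named after their values had been seen.

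A hypothesis is that samples with the same number may come from the same mice or were handled together. Counted over the 3 same-numbered pairs, 62 probe sets set a pair apart from the other arrays by over 2 log2 units. The 5 other pairings of LRC with non-LRC arrays gave at most 42. For named genes not placed on X or Y these counts were 32 and at most 21. With 6 pairings the smallest p an exact test can give is 0.167, so shared mice, shared handling and chance cannot be told apart here. If the numbers did mark shared mice, the groups would be paired, and with the number as a block limma still called 0 probe sets. The permutation tests and the splits of the arrays took no account of the numbers. For replicates 1, 2 and 3 the replication list means were 6.31, 6.85 and 6.63 in LRC and 7.29, 7.04 and 7.28 in non-LRC.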
